A study of Mus musculus with 6 samples.

How the data were processed

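The data are bulk RNA-seq of livers from 6 male Kunming mice aged 6 to 8 weeks and weighing 20 to 28 g, assigned at random to gigantol at 10 mg/kg or vehicle by mouth, with 3 mice per group, 1 liver per mouse and 1 batch label for all. Per the labels' protocols, total RNA was depleted of ribosomal RNA and made into stranded libraries. Per the submitters' processing notes, fastp, HISAT2 and DESeq2 1.16.1 were used, with no role or order stated; the read counter, the annotation and any filters are not given in the sources used here. Those notes name GRCh38, a human build, and the sample titles name the human line PANC1, yet every gene ID of the table is a mouse Ensembl ID. Of 330 genes matched by ID to the GRCm38 annotation, 318 had the same symbol and 324 the same span length but 8 the same coordinates, so coordinates are given as the table has them, on a mouse build that is not named. Samples were grouped by the treatment label.

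The deposited file is a table of the authors' comparison with 6 columns of CPM, which the header does not name as such. The CPM unit was read from the values: in each library the low values were whole multiples of 1 step, the same for every gene, as whole reads scaled by the authors to each library's size would give. All values up to 200 reads came out whole within a tolerance of 0.1 reads in all 6 libraries. The steps were used for depth, for a floor of 3 reads per library and to compare libraries with counting noise. No count test was run on the reads so worked out, so how many genes one would call is not known here. Floors cover counting error only, since reads without molecular identifiers are not independent molecules. The listed genes made up 0.637% to 0.842% of each library's CPM. The authors' log2 fold changes and p-values were deposited beside the CPM, per the file headers, with no tool named there. The ratio of the first gene's FDR to its p shows that the authors adjusted over 13192 genes. Every row had a p of at most 0.0499 and an absolute log2 fold change of at least 1.00, so the table is a selection made on these same libraries; other genes were not analysed here. Of the rows, 240 were protein-coding genes and 37 pseudogenes, and 118 had a mean under 1 CPM.

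The test fixed for normalized values before the data were examined was limma 3.58.1 in R 4.3.3, two-sided, on log2(CPM + 1) of genes with at least 1 CPM in at least 3 libraries, with trended and robust variance moderation and Benjamini-Hochberg adjustment at 0.05; fold changes on this scale understate those of low genes. It covered 201 genes, and 131 were not tested. Adjusting within a table selected on the same libraries is circular. Simulated data illustrate this for selection by limma's own p: of 8449 simulated genes without effect, the 461 selected at an unadjusted p under 0.05 all passed when adjusted among themselves and 0 when adjusted over all. Benjamini-Hochberg adjustment always passes a set whose p are all under 0.05. The real rows were selected by the authors' p and fold change instead. A gene is therefore said to have risen or fallen where its FDR in the authors' deposited table, adjusted over 13192 genes, was under 0.05. The limma values beside it give size and spread and are not independent evidence, and limma p-values were also adjusted over 13192 genes, a choice made after seeing the data. That adjustment had the p of the 201 tested genes alone and ranked every gene without a limma p after them. The variance moderation also used the selected rows alone. Its counts are therefore not those of a limma fit to all 13192 genes. On the 233 of the simulated genes of the same levels (dispersion 0.05) that passed the filter, limma recovered 93.1% of 72 genes changed 2-fold and 100% of 77 changed 4-fold, and called 6 of 84 unchanged genes. That dispersion was set and not estimated from these livers, so the rates need not hold for them. Of the 201 real genes tested, all with an absolute log2 fold change of at least 1.00 by the authors, limma passed 111 adjusted over the table. The 3 libraries of each group differed from each other by far more than counting noise (chi-square per gene 30.5 to 244), so no library was counted as a repeat of another.

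Fixed beforehand were 45 gene lists with 982 symbols and a panel of 24 PPAR genes, of which 59 distinct list genes and 1 panel gene were analysed here. An adjustment over the list alone covered only the tested members of that list, all of them preselected. It passes every member where all have an unadjusted p under 0.05, and it leaves the p of a single tested member unadjusted. Lists with at least 5 tested members (5 lists) were compared with the other tested genes by limma camera with a preset correlation of 0.01, and with an estimated one, and by limma fry, which does not compare with other genes. Since those other genes were all selected as changed, limma camera says only how a list stands within the table. The members that limma fry tests were themselves selected as changed in these libraries, so a small fry p is not independent evidence. The named genes were, by a rule also fixed beforehand, the 10 largest increases and 10 largest decreases by limma among genes past the table adjustment with non-overlapping groups and a mean of at least 1 CPM, passing over 6 higher and 1 lower predicted genes and pseudogenes, then every panel gene, up to 4 members of each list described, and the hepatocyte and PANC1 markers. C8b, Cyp4a32, Elovl3, Mup20 and Myc fell outside that rule and were named after their values were seen. Near-identical copies were sought with BLAST 2.17.0 for 330 genes, at 95% identity over at least 50% of the transcript against all annotated mouse transcripts. Alternatives were the replicate number as a block, each library left out, no filter, a mean of at least 5 CPM, quantile normalization, a pseudocount of 0.1, limma without trend and robust moderation, other thresholds and the removal of hemoglobin, Mup and mitochondrially encoded genes. Tables and figures were made with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.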

Results

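Liver RNA was sequenced from 6 male mice of the outbred Kunming stock, of which 3 had received gigantol by mouth at 10 mg/kg and 3 had received vehicle, all killed 4 h after dosing. Gigantol is a bibenzyl found in Dendrobium orchids. The series title names it as an agonist of PPARα and PPARγ, the nuclear receptors that drive fatty acid oxidation genes in liver and fat storage genes in adipocytes, so the comparison asks which liver transcripts differed between dosed and undosed mice. The table analysed here lists 332 genes with their CPM (its reads scaled to the size of the library) in each library and the authors' own fold change, p and FDR. Read depths worked out from the smallest CPM steps were close to 21200000, 21300000 and 24600000 reads for the gigantol livers and 26700000, 25600000 and 23100000 reads for the vehicle livers. A single read was therefore worth 0.0374 to 0.0471 CPM, and a gene under 3 reads lay below 0.112 to 0.141 CPM. The sample titles name PANC1, a human pancreatic cancer line, whereas the organism, tissue and treatment labels and all 332 gene IDs are mouse. The columns carry those titles, so each column's group rests on the treatment label that goes with its title.

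The authors' deposited table holds 119 genes that were higher and 213 that were lower in the gigantol livers, each with an absolute log2 fold change of at least 1.00 and an unadjusted p of at most 0.0499. By the FDR of the authors' deposited table, which was adjusted over 13192 genes, 86 of them changed, 34 upward and 52 downward. The authors' p and FDR place the last of these 86 at rank 122 of the 13192, so other genes under an FDR of 0.05 are not among the 332. The 4 smallest FDRs of the authors' deposited table were those of Rcc1, Ctps2, Hsd3b5 and Xlr3a. The 3 gigantol livers lay entirely above or below the 3 vehicle livers for 83 of the 86 genes and for 239 of the 332 (72.0%), where chance gives 10% of unselected genes. These rows had been selected on the same 6 libraries, so that share is not independent evidence. With limma on log2(CPM + 1), 111 of the 201 genes with at least 1 CPM in 3 libraries had an adjusted p under 0.05 when adjusted over the table (40 higher, 71 lower). Adjusted over all 13192 genes, with each gene that had no limma p ranked after the tested ones, 9 passed (8 higher, 1 lower). The 111 fell to 57, 60, 32 and 35 without gigantol replicates 1 and 3 and vehicle replicates 2 and 3, and the 9 to 4 without gigantol replicate 1 and to 1, not among the 9, without vehicle replicate 1.

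**Figure D1:**
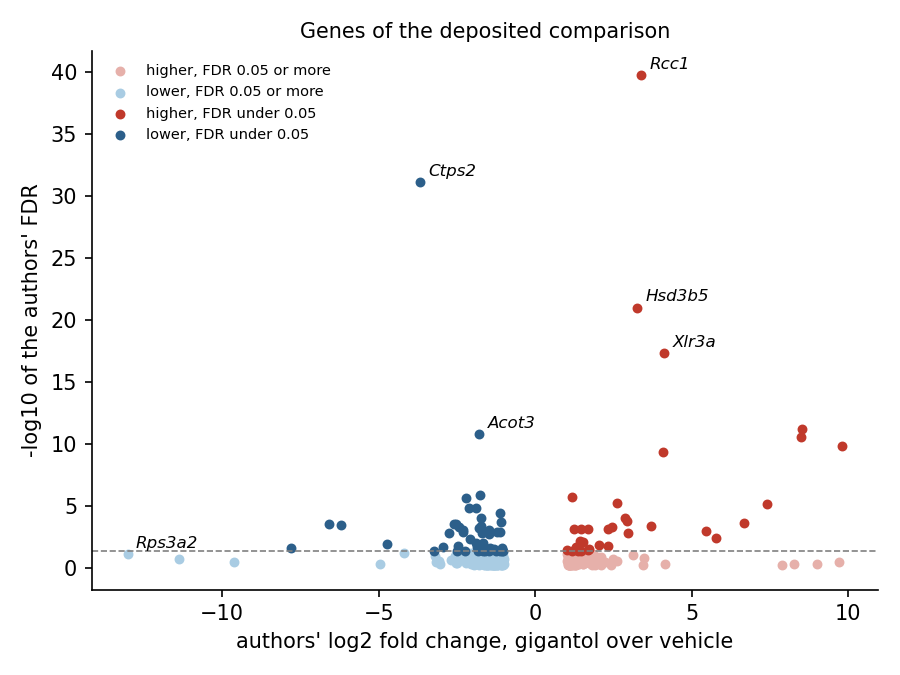
Each point is 1 of the 332 genes, with the authors' log2 fold change (gigantol over vehicle) on the horizontal axis and −log10 of the authors' FDR on the vertical axis; darker points are the 86 genes under an FDR of 0.05, marked by the dashed line. Rcc1 and Ctps2 stand highest on the 2 sides, at log2 fold changes of 3.37 and −3.68 in the authors' deposited table.

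Among genes that rose, Rcc1, the chromatin-bound exchange factor of the Ran GTPase, went from 7.11 ± 1.85 CPM in vehicle to 73.2 ± 9.68 CPM in gigantol livers (SD, n = 3 each). Kpna2, an importin alpha that carries cargo into the nucleus in a Ran-dependent cycle, was at 17.4 ± 5.54 against 0.397 ± 0.559 CPM. Hsd3b5, a hydroxysteroid dehydrogenase family member made mostly in male mouse liver, was at 22.5 ± 5.34 against 2.36 ± 0.778 CPM, and Xlr3a, an X-linked gene of the lymphocyte-regulated family, at 6.89 ± 2.42 against 0.393 ± 0.125 CPM. Ctps2, a CTP synthase and the largest limma decrease under the naming rule, fell from 13.2 ± 2.65 to 1.03 ± 0.0497 CPM. limma gave log2(CPM + 1) changes of 3.21 ± 0.444 (SE) for Rcc1, 3.74 ± 0.415 for Kpna2, 2.81 ± 0.406 for Hsd3b5, 2.46 ± 0.331 for Xlr3a and −2.79 ± 0.354 for Ctps2, with limma adjusted p over all 13192 genes of 0.0231, 0.00480, 0.0267, 0.0204 and 0.0145. The authors' deposited table gave FDRs of 2.06e-40, 0.00107, 1.09e-21, 4.78e-18 and 8.52e-32 for the same 5 genes. Rcc1 (ENSMUSG00000028896) lies on chromosome 4 from 132059230 to 132080916, Hsd3b5 (ENSMUSG00000038092) on chromosome 3 from 98525950 to 98537568, and Ctps2 (ENSMUSG00000031360) on chromosome X from 161684234 to 161815504, all as the table places them on a mouse build whose name is not given in the sources used here. The Kpna2 vehicle mean rested on vehicle replicate 3 (1.04 CPM) and was 0.0755 CPM, under 3 reads, without it. Kpna2 has 4 near-identical copies among other annotated genes and Xlr3a has 1, so their reads could have been split or pooled by the authors' counting.

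The 20 largest changes under the fixed naming rule further included, on the higher side, Ugt3a2, a UDP-glycosyltransferase (206 ± 49.2 against 33.9 ± 24.9 CPM), and Asic5, a bile acid-sensitive ion channel (39.0 ± 32.9 against 5.10 ± 3.12 CPM, SD, n = 3 each). Hamp, which encodes the iron hormone hepcidin, was at 331 ± 168 against 102 ± 17.4 CPM. On the lower side were Cyp17a1, a steroid hydroxylase (7.40 ± 5.53 against 31.7 ± 7.78 CPM), Cyp26a1, which clears retinoic acid (1.00 ± 0.718 against 5.41 ± 1.89 CPM), Wfdc2, a secreted protease inhibitor family member (3.22 ± 1.18 against 16.1 ± 9.62 CPM), and Arl4d, a small GTPase (15.9 ± 7.66 against 52.6 ± 10.8 CPM). FDRs in the authors' deposited table were 6.49e-06 for Ugt3a2, 0.000160 for Asic5, 0.000702 for Hamp, 0.00468 for Cyp17a1, 0.000561 for Cyp26a1, 0.00129 for Wfdc2 and 0.000415 for Arl4d. Of the 20, 18 passed an FDR of 0.05 in the authors' deposited table. The exceptions were Cyp4a31, described with the PPARα targets, and Scara5, a ferritin receptor, at 21.3 ± 4.42 against 8.51 ± 7.77 CPM with an FDR of 0.360 in the authors' deposited table. Asic5 rested in part on gigantol replicate 2 (77.0 CPM against 18.7 and 21.4), without which its limma log2 change went from 2.53 to 1.90. That of Wfdc2 went from −1.84 to −2.44 without vehicle replicate 1, while its limma adjusted p was 0.0571 and 0.0561 without vehicle replicates 2 and 3. Without vehicle replicate 1 the vehicle means of Ugt3a2, Asic5 and Scara5 were 19.6, 3.31 and 4.02 CPM, and without gigantol replicate 2 the gigantol means of Cyp17a1 and Cyp26a1 were 4.36 and 0.588 CPM. By limma adjusted over the table, 10 of the 20 kept an adjusted p under 0.05 without any 1 library. The other 10 lost it at limma adjusted p of 0.0511 to 0.137, with 6, 1 and 4 lost without gigantol replicates 1, 2 and 3, and 0, 9 and 9 without vehicle replicates 1, 2 and 3.

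**Figure D2:**
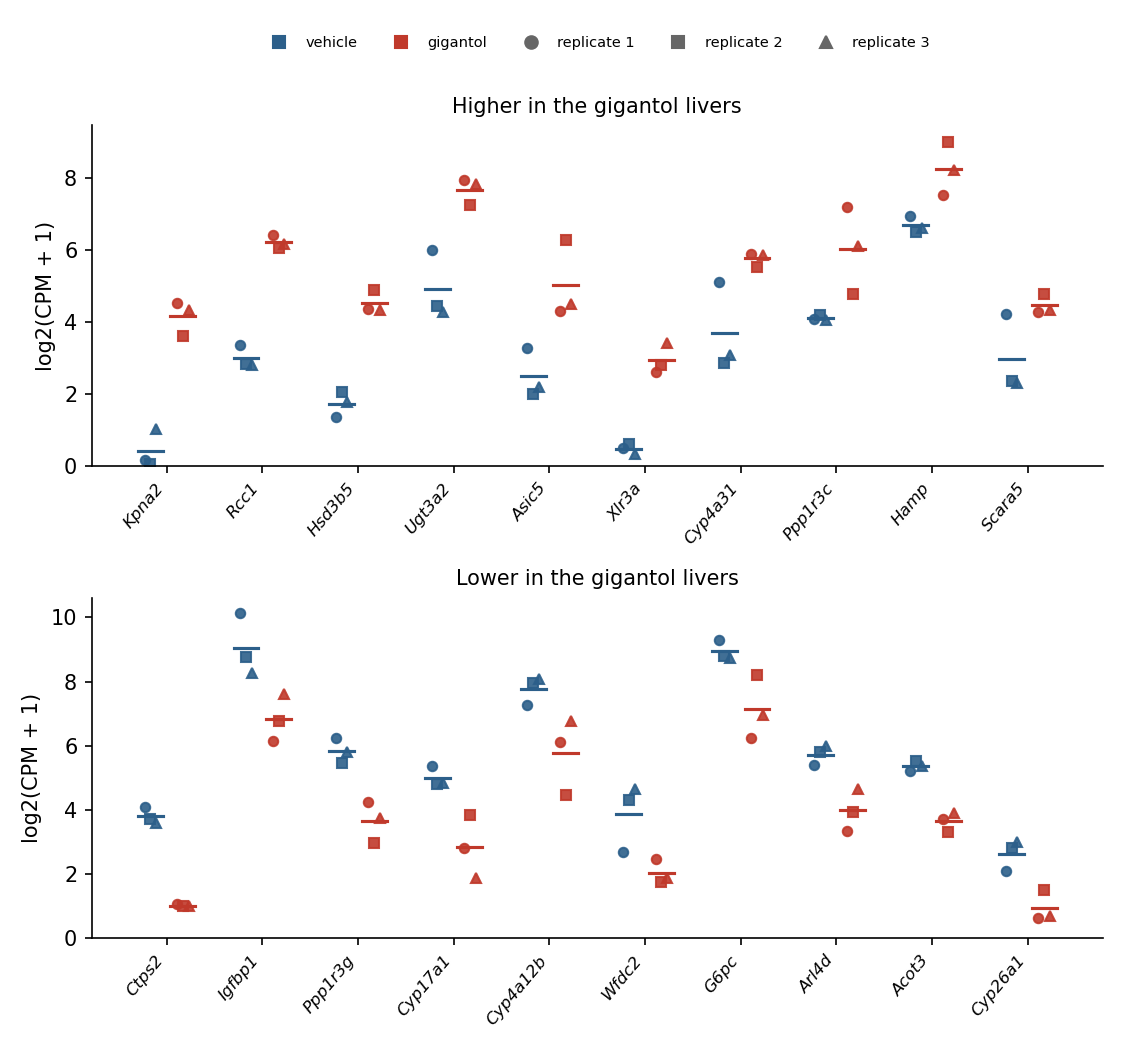
Log2(CPM + 1) of the 20 named genes in each library, with vehicle in blue, gigantol in red, the marker shape giving the replicate number and the bar the mean of 3. In every gene shown the 3 gigantol values lie on 1 side of the 3 vehicle values; the gap is smallest for Scara5, Wfdc2 and Cyp4a31, where vehicle replicate 1 (17.5, 5.39 and 33.4 CPM) is the nearest vehicle value.

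For PPARα, 5 of the 52 targets fixed for liver were among the genes analysed here, 1 higher and 4 lower. Acot3, a peroxisomal acyl-CoA thioesterase, fell from 40.2 ± 4.69 to 11.7 ± 2.60 CPM and Txnip, a thioredoxin-binding regulator of glucose uptake, from 155 ± 57.8 to 73.2 ± 10.8 CPM (SD, n = 3 each), with FDRs of 1.84e-11 and 0.0261 in the authors' deposited table. The others had mixed values. Cyp4a31, a fatty acid hydroxylase, was at 53.5 ± 7.03 against 15.7 ± 15.4 CPM, its relative Cyp4a32 at 206 ± 31.1 against 458 ± 406 CPM, and Cd36, a fatty acid transporter, at 14.1 ± 3.56 against 31.1 ± 14.8 CPM. None of these 3 passed in the authors' deposited table, with FDRs of 0.101, 0.477 and 0.112. Cyp4a31 and Cyp4a32 each have 2 near-identical copies among other annotated genes, and Cyp4a32 read 927 CPM in vehicle replicate 1 against 235 and 213 CPM in the other vehicle livers. The vehicle mean of Cyp4a31 was 6.82 CPM without that library. limma had 2 of the 5 past the threshold adjusted over the table (Acot3 and Cyp4a31, with Txnip at an adjusted p of 0.0746), 2 adjusted over the list alone and 0 adjusted over all 13192 genes. Neither Acot3 nor Cyp4a31 stayed past the table threshold in every run with 1 library left out. Against the other tested genes of the table the list did not stand apart (limma camera adjusted p = 0.401, median log2 change −1.02, mean −0.50), and limma fry gave a directional p of 0.0679 and a mixed p, for change in either direction, of 1.13e-05 on these preselected genes.

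Of the PPARγ and adipogenic list, 2 of 30 genes were among those analysed here. Plin4, a lipid droplet coat protein, rose from 5.87 ± 2.26 to 13.2 ± 3.21 CPM (SD, n = 3 each), at an FDR of 0.0473 in the authors' deposited table; the other was Cd36. By limma 1 of the 2 passed adjusted over the table and 0 adjusted over the list alone, with 1 at an unadjusted p under 0.05. The table call, that of Plin4, did not hold in every run with 1 library left out. Of the 24-gene PPAR panel, which includes the receptors themselves and the standard responders Cpt1a, Cyp4a10, Pdk4, Angptl4 and Fabp4, Cd36 alone was among the genes analysed here and the other 23 were not analysed here. limma gave Cd36 a log2 change of −1.02 ± 0.482 (SE), unadjusted p = 0.0565 and adjusted p = 0.0734. The panel count was therefore 0 over the table, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05. Without gigantol replicate 2 the limma adjusted p of Cd36 was 0.0491.

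Of the 22-gene gluconeogenesis and fasting list, 5 members were analysed here, all with lower means in the gigantol livers, and 4 of them fell past an FDR of 0.05 in the authors' deposited table. G6pc, the catalytic subunit of glucose-6-phosphatase, went from 500 ± 115 to 164 ± 115 CPM and Igfbp1, an insulin-repressed binding protein, from 621 ± 439 to 124 ± 63.9 CPM. Irs2, the insulin receptor substrate induced by fasting, went from 35.5 ± 9.58 to 11.7 ± 7.64 CPM and Slc25a25, a mitochondrial ATP-Mg carrier, from 191 ± 56.7 to 87.2 ± 27.0 CPM (SD, n = 3 each). These 4 had FDRs of 0.0398, 0.000923, 0.0473 and 0.0423 in the authors' deposited table. The fifth, Dusp1, was at 20.6 ± 11.4 against 43.1 ± 9.31 CPM, FDR 0.317 in the authors' deposited table. The vehicle mean of Igfbp1 rested on vehicle replicate 1 (1122 CPM), without which it was 370 CPM, 2.97 times the gigantol mean. Without gigantol replicate 2 the gigantol means of G6pc and Irs2 were 98.7 and 7.60 CPM. limma had 3 of the 5 past the threshold adjusted over the table (G6pc, Igfbp1 and Irs2, with Slc25a25 at an adjusted p of 0.0684), of which 0 stayed past it in every run with 1 library left out, 5 adjusted over the list alone and 0 over all 13192 genes. The list's median log2 change was −1.69 against −0.70 for the other tested genes, with a limma camera adjusted p of 0.117 (adjusted p = 0.270 with an estimated correlation, 0.0468 among genes with a mean of at least 5 CPM). The directional limma fry p was 0.00483 on these preselected genes.

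Of the 26-gene glycolysis and insulin list, 3 members were analysed here and all passed an FDR of 0.05 in the authors' deposited table, 2 upward and 1 downward. Ppp1r3b and Ppp1r3c, which bring protein phosphatase 1 to glycogen and favour its synthesis, rose from 56.6 ± 2.37 to 182 ± 125 CPM and from 16.2 ± 0.924 to 80.2 ± 60.4 CPM, and Socs2, a feedback inhibitor of growth hormone signalling, fell from 35.2 ± 15.1 to 10.1 ± 2.87 CPM (SD, n = 3 each). Ppp1r3g, a relative of Ppp1r3b and Ppp1r3c that was in none of the lists, was among the 20 genes named by size and was set beside them after its values were seen. It fell from 57.4 ± 15.9 to 12.5 ± 5.61 CPM. FDRs in the authors' deposited table were 0.0347 for Ppp1r3b, 0.000702 for Ppp1r3c, 2.37e-06 for Ppp1r3g and 0.000694 for Socs2. Of the 3 list members limma had 2 past the threshold adjusted over the table and 3 adjusted over the list alone. The gigantol livers differed widely among themselves, at 312, 63.4 and 170 CPM for Ppp1r3b and 146, 26.5 and 68.5 CPM for Ppp1r3c. With 1 library left out the limma log2 change of Ppp1r3b went from 1.39 to between 0.87 and 2.01 and that of Ppp1r3c from 1.93 to between 1.35 and 2.56, lowest without gigantol replicate 1 and highest without gigantol replicate 2. Of these runs Ppp1r3b was past the limma threshold in the one without gigantol replicate 2 alone (adjusted p = 0.0106 against 0.0604 with all libraries). Ppp1r3c was not past it without gigantol replicates 1 and 3 and vehicle replicates 2 and 3 (limma adjusted p = 0.0823, 0.0511, 0.0571 and 0.0526), nor was Socs2 (0.0731, 0.0521, 0.0925 and 0.0981).

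**Figure D3:**
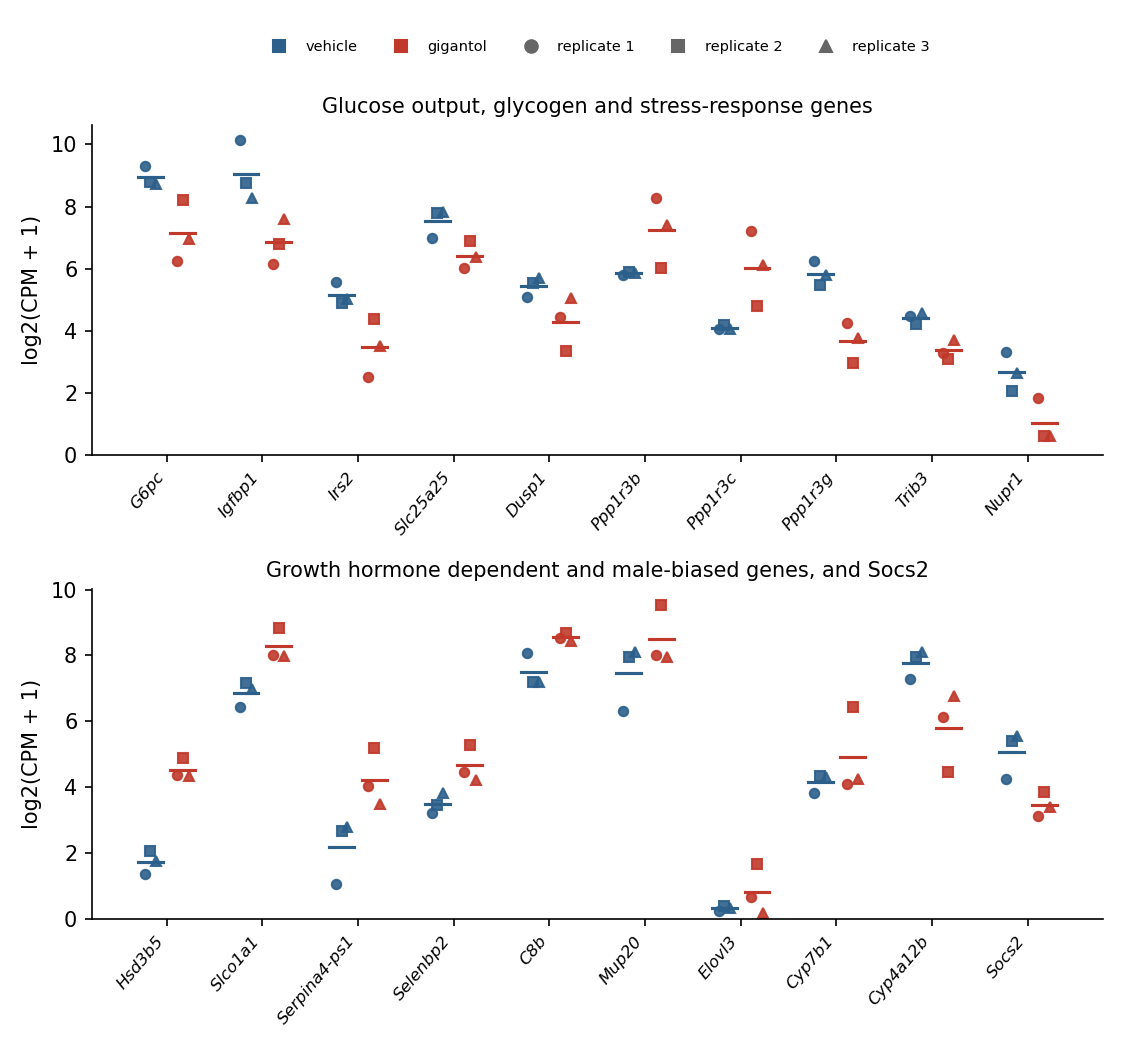
Log2(CPM + 1) in each library of genes of glucose output, glycogen and stress response (top) and of growth hormone dependent and male-biased genes with Socs2 (bottom), vehicle in blue and gigantol in red, with the replicate number as marker shape and the bar as the mean of 3. G6pc, Igfbp1, Irs2 and Slc25a25 lie lower in all 3 gigantol livers and Hsd3b5, Slco1a1 and C8b higher, while Mup20, Elovl3 and Cyp7b1 overlap between the groups.

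Of the 26 growth hormone dependent and male-biased liver genes fixed, 9 were analysed here, 8 with a higher mean and 1 with a lower one. Past an FDR of 0.05 in the authors' deposited table were 5 that rose and 1 that fell. Beside Hsd3b5 these were Slco1a1, an organic anion uptake transporter (321 ± 116 against 117 ± 28.5 CPM), C8b, a complement component (375 ± 34.8 against 187 ± 71.3 CPM), Selenbp2, a selenium-binding protein (25.6 ± 10.9 against 10.5 ± 2.52 CPM), and the pseudogene Serpina4-ps1 (20.3 ± 13.3 against 4.10 ± 2.63 CPM). Their FDRs in the authors' deposited table were 0.000708, 0.0412, 0.0238 and 0.0187. Cyp4a12b, a fatty acid hydroxylase typical of male liver, fell from 225 ± 61.7 to 65.9 ± 43.6 CPM, FDR 0.0395 in the authors' deposited table. Its limma log2 change went from −2.00 to −1.33 without gigantol replicate 2. It has 1 near-identical copy among other annotated genes, as has Selenbp2. Mup20, Elovl3 and Cyp7b1 did not pass, and the Cyp7b1 mean of 39.9 ± 39.8 CPM rested on gigantol replicate 2 (85.8 CPM against 16.0 and 18.0). That library was also high for Mup20 (745 CPM) and Elovl3 (2.16 CPM). Without it the gigantol means of Mup20, Elovl3 and Cyp7b1 were 1.27, 1.36 and 0.987 times the vehicle means. It was the highest gigantol liver for the 5 that rose as well, though in each of these all 3 gigantol livers lay above all 3 vehicle livers. The Serpina4-ps1 mean was 12.7 CPM without the same library. limma had 5 of the 8 tested members past the threshold adjusted over the table, with C8b at an adjusted p of 0.0734, and of the 5 Hsd3b5 and Serpina4-ps1 stayed past it without any 1 library; it had 5 adjusted over the list alone and 1 over all 13192 genes. Their median log2 change was 1.11 against −0.73 for the other tested genes, with a limma camera adjusted p of 0.0258 (adjusted p = 0.270 with an estimated correlation, 0.0835 without gigantol replicate 2).

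Female-biased liver genes went both ways. All 4 of the 20 fixed genes that were analysed here passed an FDR of 0.05 in the authors' deposited table, 2 upward and 2 downward. Ntrk2, a neurotrophin receptor, and A1bg, a plasma glycoprotein, rose to 2.90 ± 1.73 and 3.20 ± 2.73 CPM from 0.401 ± 0.0892 and 0.414 ± 0.144 CPM, whereas Cyp17a1 and Acot3 fell (SD, n = 3 each). FDRs in the authors' deposited table were 0.000107 for Ntrk2 and 0.00176 for A1bg. limma had all 4 past the threshold adjusted over the table and 4 adjusted over the list alone, but only Cyp17a1 and Ntrk2 stayed past it without any 1 library. A1bg had a limma adjusted p of 0.0505 without vehicle replicate 1, and Acot3 0.0648 and 0.0526 without vehicle replicates 2 and 3. The A1bg mean rested on gigantol replicate 3 (6.30 CPM; the mean without it was 1.65 CPM) and that of Ntrk2 on gigantol replicate 1 (4.90 CPM; 1.90 CPM without it). The list was too small for a list test.

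Bile acid and drug metabolism genes passed in few cases. Of the 24 bile acid genes 4 were analysed here, and Slco1a1 alone passed an FDR of 0.05 in the authors' deposited table. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at 72.1 ± 58.8 against 181 ± 21.6 CPM, and Slc51a, a subunit of a bile acid exporter, at 0.491 ± 0.305 against 1.43 ± 0.991 CPM (SD, n = 3 each), with FDRs of 0.222 and 0.581 in the authors' deposited table. Without gigantol replicate 2 (140 CPM) the gigantol mean of Cyp7a1 was 38.2 CPM. Both members of the 30-gene CAR and PXR list that were analysed here had higher means without passing. Cyp2b10, the usual CAR target, was at 138 ± 70.8 against 57.5 ± 9.28 CPM and Gadd45b at 9.85 ± 3.21 against 4.86 ± 0.603 CPM, with FDRs of 0.104 and 0.0850 in the authors' deposited table. limma passed 2 of the 3 tested bile acid genes (Slco1a1 and Cyp7a1) and 0 of the 2 CAR and PXR genes adjusted over the table, and likewise 2 and 0 adjusted over the list alone. Neither Slco1a1 nor Cyp7a1 stayed past the table threshold in every run with 1 library left out. Of the CAR and PXR genes 0 had an unadjusted limma p under 0.05.

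Of the integrated stress list 2 genes changed. Trib3, a pseudokinase induced by the integrated stress response, fell from 20.5 ± 2.83 to 9.46 ± 2.31 CPM and Nupr1, a stress-induced chromatin protein, from 5.80 ± 2.95 to 1.21 ± 1.19 CPM (SD, n = 3 each), with FDRs of 0.00135 and 0.0473 in the authors' deposited table. The Nupr1 gigantol mean rested on gigantol replicate 1 (2.59 CPM) and was 0.522 CPM without it. Trib3 and Nupr1 were the 2 of 29 list members analysed here, and limma passed both adjusted over the table, with Nupr1 alone staying past it in every run with 1 library left out, and both adjusted over the list alone. All 5 of the 29 immediate early genes analysed here had lower means, and Sgk1, a kinase induced by glucocorticoid and serum, passed, from 51.7 ± 6.84 to 23.4 ± 4.23 CPM, FDR 3.70e-05 in the authors' deposited table. Egr1 (6.56 ± 0.753 against 15.5 ± 10.3 CPM), Ier3 (0.586 ± 0.199 against 1.47 ± 0.251 CPM), Myc and Dusp1 did not pass, with FDRs of 0.190, 0.201, 0.325 and 0.317 in the authors' deposited table. Without vehicle replicate 1 the vehicle mean of Egr1 was 9.55 CPM. limma called other genes of this list: Ier3 and Myc were past the threshold adjusted over the table (adjusted p = 0.0230 and 0.0477), neither in every run with 1 library left out, and Sgk1 was not (0.0513), with 3 past it adjusted over the list alone. The list had a limma camera adjusted p of 0.158 (adjusted p = 0.270 with an estimated correlation) and a directional limma fry p of 0.000552 on these preselected genes.

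Hamp was the 1 member of both the iron list and the acute phase list to pass. Orm3, an acid glycoprotein, was at 3.65 ± 1.37 against 9.47 ± 3.86 CPM, and the chemokine gene Cxcl1 at 33.7 ± 36.0 against 9.59 ± 3.16 CPM (SD, n = 3 each), with FDRs of 0.0553 and 0.565 in the authors' deposited table. Of the p53 list, Cdkn1a, a cell cycle inhibitor, was at 20.8 ± 9.39 against 8.14 ± 5.09 CPM and Ddit4, an mTOR inhibitor that was also the 1 hypoxia gene, at 17.5 ± 12.8 against 46.2 ± 5.95 CPM, neither past an FDR of 0.05 (0.210 and 0.159 in the authors' deposited table). Single libraries carried the differences of Cxcl1 (gigantol replicate 3, gigantol mean of 12.9 CPM without it) and Vldlr (vehicle replicate 1, vehicle mean of 9.24 CPM without it). In Ddit4 and Cdkn1a a single library narrowed the difference instead. Without gigantol replicate 3 the gigantol mean of Ddit4 was 10.5 CPM, and without vehicle replicate 1 the vehicle mean of Cdkn1a was 5.21 CPM. Arntl, the 1 core clock gene, was at 2.64 ± 1.02 against 1.28 ± 0.157 CPM, Vldlr, the 1 lipoprotein gene, at 6.26 ± 0.819 against 14.1 ± 8.45 CPM, and Thbs1, the 1 gene of the epithelial-mesenchymal list, at 1.34 ± 0.874 against 3.25 ± 1.31 CPM. None passed, with FDRs of 0.304, 0.186 and 0.495 in the authors' deposited table. Rps18, the 1 ribosomal protein gene, had an FDR of 0.0134 in the authors' deposited table, resting on vehicle replicates 2 and 3 at 244 and 288 CPM. Vehicle replicate 1, at 6.93 CPM, lay inside the gigantol range of 5.70 to 8.31 CPM. By limma adjusted over the table, 2 of 3 acute phase genes (Hamp and Orm3), 1 of 2 p53 genes (Ddit4) and the single iron, hypoxia and ribosomal genes passed, and adjusted over the list alone 2, 2, 1, 1 and 1. None of these table calls held in every run with 1 library left out. The single clock and lipoprotein genes had unadjusted limma p above 0.05, and Thbs1 had an adjusted p of 0.0565 over the table. It passed adjusted over the list alone only because, as the single tested member, it kept its unadjusted limma p of 0.0343.

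All 7 erythroid genes analysed here, of 16 fixed, had lower means in the gigantol livers, and 1 passed. Hba-a2, an alpha-globin gene with 1 near-identical copy, fell from 108 ± 33.8 to 38.9 ± 10.9 CPM (SD, n = 3 each), at an FDR of 0.000966 in the authors' deposited table. Its copy Hba-a1 overlapped between the groups and did not pass, with an FDR of 0.491 in the authors' deposited table and a limma log2 change of −0.918. The beta-globin gene Hbb-bs was at 218 ± 51.5 against 501 ± 303 CPM and did not pass, with an FDR of 0.196 in the authors' deposited table. The erythroid list had a limma camera adjusted p of 0.170 (adjusted p = 0.553 with an estimated correlation), with 1 of 6 tested members past the threshold adjusted over the table and 0 adjusted over the list alone, although 3 had an unadjusted limma p under 0.05. The 1 table call, that of Hba-a2, did not hold in every run with 1 library left out. Marco, a scavenger receptor of Kupffer cells, the resident macrophages of liver, fell from 8.62 ± 0.360 to 2.60 ± 1.08 CPM, and Mpo, a granulocyte peroxidase, had a lower mean of 0.230 ± 0.161 against 2.18 ± 2.52 CPM with overlapping groups. The Mpo vehicle mean rested on vehicle replicate 1 (5.06 CPM) and was 0.738 CPM without it, 3.21 times the gigantol mean. Marco and Mpo had FDRs of 0.000107 and 0.0479 in the authors' deposited table. The stellate cell genes Lrat (7.77 ± 1.75 against 16.0 ± 5.56 CPM) and Des (1.67 ± 0.823 against 3.87 ± 0.452 CPM) and the lymphocyte genes Nkg7, Cd8a and Cd79a, all under 1 CPM, had lower means at FDRs of 0.121 to 0.576 in the authors' deposited table. By limma adjusted over the table, Marco and Des passed (adjusted p = 0.0138 and 0.0477) and Lrat did not (0.0746). Neither call held in every run with 1 library left out. The other 22 of the 45 lists, among them fatty acid oxidation, fatty acid and cholesterol synthesis, interferon response, cell cycle, hepatocyte markers and PANC1 markers, had no member among the genes analysed here, so the tissue of origin was not checked with the fixed markers. Slco1a1 and C8b, of the fixed male-biased liver list, were read at 85.7 to 455 and 146 to 414 CPM over the 6 libraries.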

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

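The adjustment over all genes the authors tested, the count by the authors' FDR, and, for the gene lists, the pseudocount, the mean of at least 5 CPM and the removal of hemoglobin and Mup genes were chosen after the data were seen; all other alternatives were planned. The 111 genes past the limma threshold (40 higher, 71 lower) became 169 without a filter (51 and 118), 24 at a mean of at least 5 CPM (9 and 15), where 101 genes were tested, and 9 adjusted over all 13192 genes, and they ranged from 32 to 136 with 1 library left out. Quantile normalization moved the median log2 change of the tested genes from −0.72 to −0.48 and the split to 46 higher and 31 lower, with 0 genes changing sign; the cause of the other shifts was not tested. The other alternatives, apart from the replicate block, gave 76 to 110 genes. The PPAR panel count of 0 ranged from 0 to 1 with 1 library left out, the 1 being Cd36 without gigantol replicate 2. The count of 1 list, the male-biased genes, was 0 with an estimated correlation (0 also at an unadjusted p under 0.05 by limma camera) and ranged from 0 to 1 with 1 library left out, the 0 being without gigantol replicate 2. It was 0 with a pseudocount of 0.1 (limma camera adjusted p of 0.0600) and 2 at a mean of at least 5 CPM, where 3 lists were large enough to test and the fasting list also passed (limma camera adjusted p of 0.0468). Of 716 results for 56 named genes under these alternatives 567 kept direction and side of the threshold, 124 lost the threshold, 24 gained it and 1 reversed: Cyp7b1 had a log2 change of −0.00175 without gigantol replicate 2, the lowest with 1 library left out, where the highest was 1.18. Fitting the replicate number as a block gave 128 genes (46 higher, 82 lower), but same-numbered livers deviated together in 2 of 3 pairs only (residual correlations of 0.13, 0.15 and −0.10), not every liver correlated best with its own number, and nothing in the labels pairs them. Settings for counts (TMM, median-ratio and library-size scaling, DESeq2) were not run because no count test was, and the hemoglobin and Mup rows were dropped without rescaling the CPM. Of the 10 splits of the 6 libraries into 3 and 3, the real one was the 1 that called as many as 111 genes, and the highest of the others called 2; the rows had been selected on the real split and 10 splits cannot give a share under 0.05.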

Other observations

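The gene groups of the first 2 paragraphs were chosen after their values were seen, as were the tests of inherited differences, of the direction of neighbouring genes between the groups, of the share of blood and of feeding; the tests of shared copies and of neighbouring genes within groups were fixed before their results were seen. Gbp11 and Gbp8, guanylate-binding proteins of the interferon-induced GTPase family, fell, to 1.78 ± 0.472 against 5.98 ± 0.403 CPM and 1.38 ± 0.238 against 3.80 ± 0.789 CPM (SD, n = 3 each), with FDRs of 1.29e-06 and 0.00187 in the authors' deposited table. Of the Cd300 family of myeloid receptors, Cd300c2 and Cd300ld3 were lower (FDRs of 0.0156 and 0.0468 in the authors' deposited table), whereas Cd300e was at 6.48 ± 5.66 against 1.61 ± 0.173 CPM with overlapping groups. The platelet chemokine genes Ppbp (0.979 ± 0.461 against 5.61 ± 3.31 CPM) and Pf4 (0.862 ± 0.238 against 2.02 ± 0.206 CPM) had lower means, at FDRs of 0.000293 and 0.110 in the authors' deposited table. Without vehicle replicate 1 (9.44 CPM) the vehicle mean of Ppbp was 3.70 CPM, and without gigantol replicate 1 (12.3 CPM) the gigantol mean of Cd300e was 3.55 CPM. Of the 5 Ifi200 family DNA sensor genes, Ifi205, Ifi208, Ifi213 and Mndal had lower means and none passed an FDR of 0.05 in the authors' deposited table (0.0908 to 0.534). The fifth, Ifi202b, was listed at 0 in all vehicle livers and in gigantol replicate 1 but at 3.29 and 1.91 CPM in the other gigantol livers.

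Cish, which like Socs2 is a target of STAT5 downstream of the growth hormone receptor, was at 6.71 ± 3.78 against 17.1 ± 3.75 CPM, with an FDR of 0.0587 in the authors' deposited table. The hepatokine gene Inhbe was higher (39.0 ± 6.55 against 17.3 ± 1.07 CPM, SD, n = 3 each), as were G0s2, an inhibitor of triglyceride lipase (27.7 ± 11.8 against 10.4 ± 3.87 CPM), and Adrb3, an adrenergic receptor gene (4.52 ± 3.09 against 0.833 ± 0.101 CPM). Without gigantol replicate 2 the gigantol mean of Adrb3 was 2.74 CPM. FDRs in the authors' deposited table were 2.20e-06, 0.0368 and 0.000557 for these 3. All 4 histone genes of the table (H2bc6, H2bc12, H4c8 and H4c9) had lower means and 0 passed an FDR of 0.05 in the authors' deposited table. Vehicle replicate 1 lay inside the gigantol range for 71 of the 332 genes (21.4%), against 25 and 23 for vehicle replicates 2 and 3. It was at least 4-fold under both other vehicle livers in 19 genes, as in Rps3a2 (listed at 0 in vehicle replicate 1 and all gigantol livers, at 111 and 94.4 CPM in the other vehicle livers), and at least 4-fold over both in 9.

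For 12 genes every liver of 1 group was above 3 reads and every liver of the other at 3 reads or fewer, 6 seen with gigantol (BC018473, at 6.92 to 12.8 CPM, Capza1-ps1, Gm7292, Gm14253, Gm4767 and Gm48417) and 6 with vehicle (Gm6644, Gm6166, Tspyl5, Gm36161, Mtus2 and AI314278). Near-identical copies were more common among these genes, at 8 of the 12 against 69 of the other 318 genes searched (odds ratio 7.22, one-sided Fisher's exact test, p = 0.00140). The same annotated copies apply to every library, so sharing reads with a copy would not by itself separate the groups. The excess of copies therefore cannot decide whether shared reads played a part. Pseudogenes made up 5 of the 12 against 32 of the other 318 (odds ratio 6.38, two-sided Fisher's exact test, p = 0.00599). The excess of copies was therefore not separated from gene type. Inherited differences between outbred mice also stay open. In the vehicle group 9 genes of the table were at 3 reads or fewer in 1 liver and at 20 or more in another, and in the gigantol group 8 were. Of the 9 in the vehicle group, 5 were off in vehicle replicate 1 alone, 2 differed so between vehicle replicates 2 and 3, and 5 have a near-identical copy. The 8 in the gigantol group were not all off in the same liver. Ifi202b was at 0 in gigantol replicate 1, Tnr in gigantol replicate 2 and Rps2-ps13 in gigantol replicate 3. Over all genes of the table, 129 pairs of neighbours within 1 Mb deviated together within groups, as shared haplotypes or shared regulation would give. Their median residual correlation was 0.152 (one-sided permutation test with 10000 shuffles of position, p = 0.0356). Without pairs in which 1 gene is a near-identical copy of the other, 122 pairs were left (same permutation test, p = 0.0446). Between the groups 51.2% of the 129 pairs changed in the same direction against 53.9% with positions shuffled (one-sided permutation test, p = 0.744). That share cannot exclude haplotypes behind the group differences, since neighbours on 1 haplotype need not change in the same direction. An effect of gigantol on these genes stays open and untested.

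Hemoglobin and other erythroid genes had lower means in the gigantol livers, Hba-a2 alone past an FDR of 0.05 in the authors' deposited table, which may reflect less blood left in them. The ratio of Hbb-bs to Hbb-bt differed by 1.24 times at most over the 6 livers, which decides nothing, since both come from red cells and their ratio would hold whatever set the amount. Summed beta-globin was 184, 290 and 295 CPM in gigantol and 283, 974 and 507 CPM in vehicle livers, so vehicle replicate 1 lay inside the gigantol range. The ratio of Hba-a2 to its near-identical copy Hba-a1 was 0.801 in vehicle replicate 1 and 0.132 to 0.201 in the others. Hba-a1 itself overlapped between the groups, so the lower Hba-a2 could in part reflect how reads were divided between the copies. Whether blood content, the division of reads between copies, gigantol or chance between 3 livers set the difference was not resolved.

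The lower G6pc, Igfbp1, Irs2 and Slc25a25 is the direction that feeding or insulin gives in liver; of the glycolysis and insulin list Ppp1r3b and Ppp1r3c rose and Socs2 fell, and outside it Ppp1r3g fell. A later or larger last meal in the gigantol mice and an action of gigantol on glucose metabolism could both produce it. All 5 of the 5 fasting genes analysed here had lower means, which either would give, and the labels record no feeding times or blood glucose, so the explanations cannot be told apart with these data.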
